A study of Homo sapiens with 9 samples.

How the data were processed

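Gene expression was measured on 9 Affymetrix arrays carrying 54675 probe sets, 3 arrays for each of 3 cell populations from fresh human bone marrow. Per the labels' protocols, the marrow was passed over ficoll, CD34+ cells were collected with magnetic beads, and a FACS Aria cell sorter separated the populations by surface antigens. RNA came from marrow of 3 different people, was extracted with a Qiagen micro kit and labelled with biotin. Each array was assigned to its population and replicate number by its label.

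The deposited values are intensities, one per probe set and array, and RMA (background correction, quantile normalization and median polish of the probes of a set) with the affy package is named without versions in the submitters' processing notes. The step that turned RMA's log2 output into linear intensities is not given in the sources used here. On every array the highest deposited intensity lies between 2413968 and 3374933, more than a 16-bit scanner can record. The natural logarithms of all values lie between 1.34 and 15.03, a range usual for log2 values from RMA. The natural logarithm was therefore taken as the log2 value, and levels and differences are called log2 units below. The base remains an inference: if the deposited intensities were truly linear, every log2 difference would be 1.44 times the one printed, while the tests and calls would be the same. The planned design named the log2 of linear values, so this choice departs from it in scale only.

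Probe sets were named through the platform annotation: 41097 had 1 gene symbol, 1801 had several and 11777 were unnamed here. Symbols were brought up to date by gene identifier for 41043 of the single-gene probe sets, and 54 kept the annotation's symbol. The 63 probe sets of XIST and its neighbours and of the Y chromosome were left out. For each gene the probe set with the highest mean over the 9 arrays was used, giving 19738 genes, of which 10509 had more than 1 probe set. The chosen probe set ends in _s_at for 4582 genes and in _x_at for 1253 genes, endings that mark probes shared between transcripts, so such values can include related transcripts. Of the genes in the fixed lists, 323 of 349 members had a value, and the others were not analysed here.

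Populations were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 3 population means fitted to all 9 arrays, a 2-sided moderated test per gene and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05. A moderated F-test counted genes that differed among the 3 populations. Errors given with differences are standard errors (SE) from this fit, and errors given with levels are standard deviations (SD) over 3 arrays. Tables were read with the data.table package (version 1.17.8) and plots drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision.

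Before the data were examined, 26 gene lists were fixed from general knowledge of marrow: sort markers, haematopoietic stem cell genes, HOXA cluster and cofactors, early lymphoid genes, V(D)J recombination, B-lineage genes, mature B cell, plasma cell, T-lineage, NK cell and plasmacytoid dendritic cell markers, granulocyte-monocyte progenitor genes, mature monocyte and mature neutrophil markers, erythroid genes, megakaryocyte genes, eosinophil, basophil and mast cell genes, stromal and endothelial cell markers, cell cycle genes, immediate early and stress genes, MHC class II genes, NOTCH pathway genes, cytokine receptors, homing and adhesion receptors, and genes of other tissues. Of these, 23 were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. The sort markers and the genes of other tissues were not tested as lists, and the HOXA list had only 2 measured members. Camera asks whether a list's genes moved more than other genes. It was also run with the correlation estimated per list, as was fry, whose directional p asks whether a list's genes move, on balance, one way without comparing them with other genes. The estimates came from the fit without the replicate number. Camera with an estimated correlation also uses fewer degrees of freedom, so a lost call need not come from correlation. Megakaryocyte genes in CD34+CD10-CD62Lhi vs CD34+CD38- had an estimate of 0.00677, below the preset. Their adjusted p by camera still rose from 3.59e-07 to 0.0176.

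The genes named were chosen by a rule set in advance. For each comparison it took the sort markers, the 10 largest differences in each direction among called genes whose arrays did not overlap, up to 4 called members of each list by size (or the 2 largest where fewer than 2 were called), and a fixed set: DNTT, IL7R, FLT3, RAG1, RAG2, CD79A, PAX5, EBF1, VPREB1, MPO, CEBPA, GATA1, CD7 and HLF. Among called named genes, 0 had another probe set called in the opposite direction.

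The replicate numbers occur in every population, so it was checked whether they pair the arrays. Deviations from the population means correlated between arrays of the same number with r from 0.362 to 0.576 across genes in all 9 pairs, and between arrays of different numbers in different populations with r from -0.438 to 0.0366 in 18 pairs. All 9 arrays correlated best with the arrays of their own number. The numbers were therefore read as pairing the arrays. The pairing comes from the numbers in the titles and this check, since the labels do not state what a number marks. The planned comparison without the number stays the main one. Fits with arrays left out did not use the number either, so the fit with the block was not tried in that way. Values with the number as a block are printed beside a result where they change its call or move its count by more than 1.5 times. For lists that did not pass camera, and for their members, this was done only in part.

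Other settings tried were the mean of a gene's probe sets, leaving out _x_at and _s_at probe sets, leaving out dim genes, quantile normalization, median centring, the replicate block, fits of only 2 populations, eBayes with trend and robust options, array weights, a minimum difference of 1, and each array left out in turn. After the data were seen, 4 more were added: the size threshold on the other log scale, the level of the BioB hybridisation control as a covariate, leaving out the 3 arrays numbered 1, and the block with a minimum difference of 1. The arrays numbered 2 or 3 were not left out as a set. Falls without number 1 therefore cannot be told apart from the effect of having fewer arrays.

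The fits were tested on simulated data for the 19738 genes with 50 genes changed at each size and with the observed shifts between replicate numbers. For CD34+CD10-CD62Lhi vs CD34+CD38- the fit without the block recovered 0%, 52%, 80% and 94% of genes changed by 1, 2, 3 and 4 log2 units, and the fit with it recovered 2%, 88%, 92% and 98%. In the comparison CD34+CD10+ vs CD34+CD38- these shares were 2%, 52%, 86% and 98% without the block and 18%, 82%, 90% and 100% with it. The simulated comparison CD34+CD10+ vs CD34+CD10-CD62Lhi gave 0%, 44%, 82% and 98% without the block and 4%, 86%, 92% and 100% with it. False calls made up 0.877%, 0.833% and 1.75% of all calls without the block in these 3 comparisons, and 6.04%, 4.61% and 7.84% with it. Differences of about 1 log2 unit were thus mostly out of reach. The residual variances of these simulations were drawn from the prior that limma fitted; a first version, which drew them from the moderated variances of the genes, gave a higher false share with the block, above the nominal 5%, and was replaced after that was seen. With the final version the block's share stays above 5% in 2 of the 3 comparisons, with 9 of 149 and 12 of 153 calls false. Each share rests on a single simulated set. The counts with the block may therefore hold more false calls than that nominal share, but these few sets cannot tell. A simulated shift of 1.5 in the erythroid list for CD34+CD10-CD62Lhi vs CD34+CD38- was found by camera (adjusted p = 2.06e-34), and 0 of the other 22 lists were called. That list simulation drew noise independently for each gene and left out the shifts between replicate numbers. It therefore cannot tell how often camera with the preset correlation falsely calls lists of correlated genes. In the data the estimated correlation reached 0.633, for cell cycle genes.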

Results

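Transcript levels were measured on 9 arrays of RNA from human bone marrow progenitors that carry CD34, a surface protein of stem and progenitor cells. The 3 sorted populations, with 3 arrays each, were CD34+CD38- cells, the fraction that holds haematopoietic stem cells; CD34+CD10- cells with strong staining for CD62L, written CD34+CD10-CD62Lhi here; and CD34+CD10+ cells, which carry the neprilysin antigen found on B-lymphoid progenitors. The series title places the start of lymphoid priming before CD10 appears. Levels are given in log2 units, taken as the natural logarithm of the deposited intensity; were those intensities linear, each difference would be 1.44 times larger. The array medians averaged 5.13 ± 0.04 (SD, n = 9), and arrays of one population correlated with r from 0.910 to 0.965 across the genes tested. As a background level, 25 genes of other tissues (liver, muscle, lens and the like) had a median of 4.36 and a 95th percentile of 5.65. Means up to 5.65 are read as not above background, and a difference that reaches such a mean, for PAX5 or LYZ for example, as a lower bound on its size whose rank among differences carries no meaning. Of the genes called below, 98 of 191, 360 of 784 and 212 of 531 have 1 of their 2 populations there, and 11, 34 and 20 have both.

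Of 4 sort markers 3 had a value, and they served as a check of the CD34, CD38 and CD10 labels only. MME, which encodes CD10, was at 10.23 ± 0.77 (SD, n = 3) in CD34+CD10+ cells, 6.30 ± 0.42 in CD34+CD10-CD62Lhi cells and 6.16 ± 0.22 in CD34+CD38- cells. CD38 was at 5.97 ± 0.27 in CD34+CD38- cells, 7.82 ± 0.16 in CD34+CD10-CD62Lhi cells and 8.37 ± 0.58 in CD34+CD10+ cells. CD34 was at 9.70 ± 0.55, 8.31 ± 0.62 and 8.22 ± 0.37 in CD34+CD38-, CD34+CD10-CD62Lhi and CD34+CD10+ cells. The difference in CD34 was not called against either population (adjusted p = 0.163 and 0.0791) but passed with the replicate number as a block (adjusted p = 0.0408 and 0.0204). By the F-test 898 of 19738 genes differed among the populations, and 2324 did with the replicate block. The second principal component, with 26.1% of the variance, lay almost wholly between populations (99.4%), while 62.5% of the first component, with 28.2% of the variance, lay between replicate numbers.

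**Figure D1:**
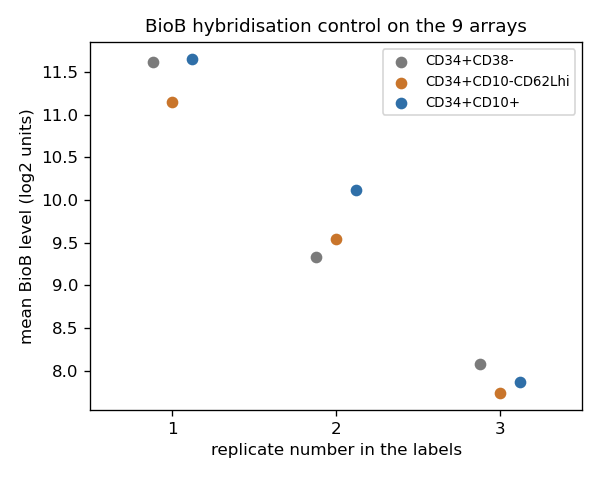
Level in log2 units (vertical axis) of the BioB hybridisation control on each of the 9 arrays (dots) by replicate number (horizontal axis). The means were 11.47, 9.67 and 7.89 for numbers 1, 2 and 3.

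**Figure D2:**
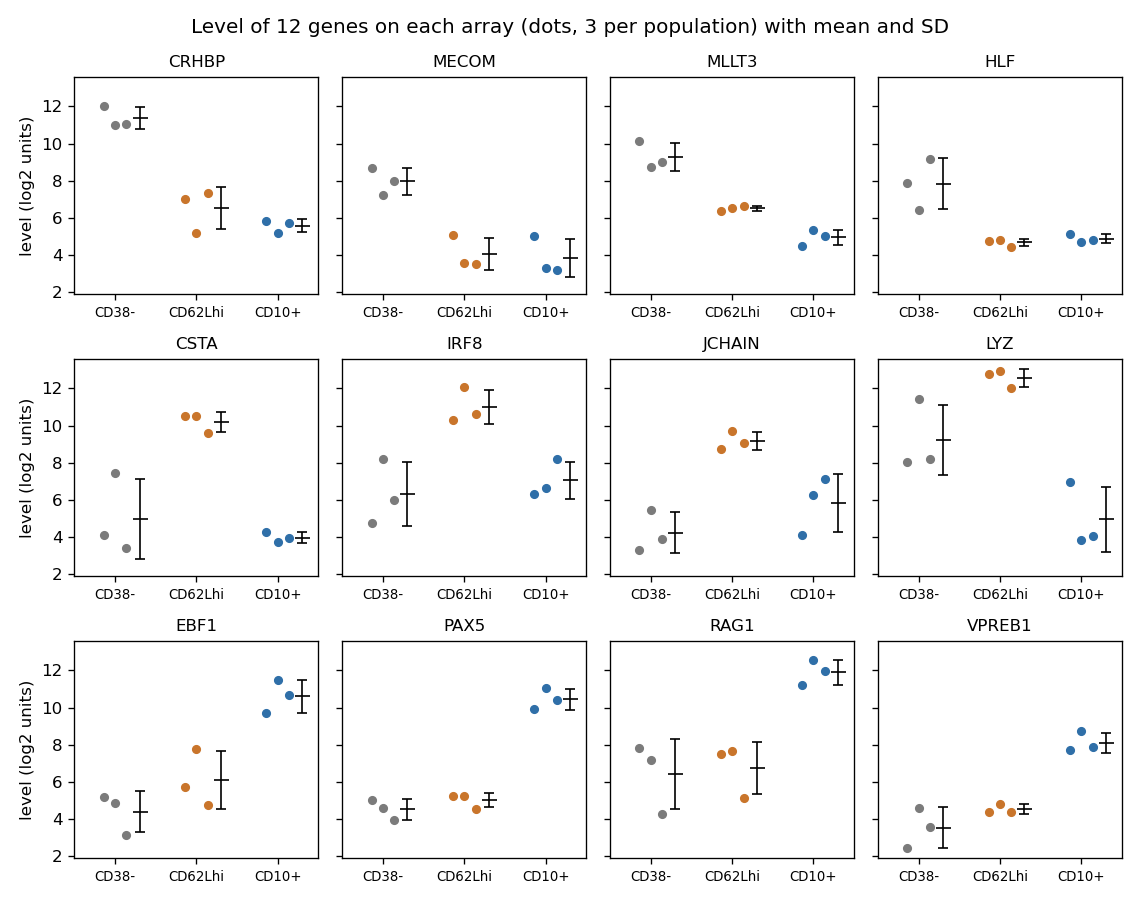
Level in log2 units (vertical axis) of 12 genes on each array (dots, 3 per population, shown by population on the horizontal axis), with the mean and SD beside them. By their means CRHBP, MECOM, MLLT3 and HLF were highest in CD34+CD38- cells, CSTA, IRF8, JCHAIN and LYZ in CD34+CD10-CD62Lhi cells, and EBF1, PAX5, RAG1 and VPREB1 in CD34+CD10+ cells, where the mean of RAG1 was 11.90. JCHAIN and LYZ were not among the genes called higher in CD34+CD10-CD62Lhi cells than in both other populations.

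The comparison of CD34+CD10-CD62Lhi with CD34+CD38- cells asks what distinguishes CD62Lhi cells sorted without CD10 from the stem cell fraction. Stem cell genes were lower in CD34+CD10-CD62Lhi cells. CRHBP, a binding protein of corticotropin-releasing hormone that marks human stem cells, was at 6.51 ± 1.16 (SD, n = 3) against 11.36 ± 0.60, a log2 difference of -4.85 ± 0.54 (SE, adjusted p = 0.00612). MECOM and HLF, transcription factors that maintain stem cells, differed by -3.92 ± 0.61 and -3.16 ± 0.56. MYCT1 and ALDH1A1, a retinaldehyde dehydrogenase, differed by -4.36 ± 0.65 and -3.65 ± 0.40. Of the 19 haematopoietic stem cell genes measured, 10 were lower and 0 higher, and 16 were lower when adjusted over the list alone. The list's median difference was -1.70 (camera, adjusted p = 1.99e-21, and adjusted p = 0.0176 with an estimated correlation). Among megakaryocyte genes 3 of 10 were lower, and 7 when adjusted over the list alone: SELP (P-selectin), ITGA2B (the platelet integrin chain) and RAB27B (a GTPase of granule release), with -3.84, -2.67 and -1.72; 5 were lower with the block. That list's median was -1.75 (camera, adjusted p = 3.59e-07, and adjusted p = 0.0176 with an estimated correlation). Of 16 erythroid genes 1 was lower, TAL1, a transcription factor also active in stem cells, at -2.84 ± 0.24 on an _s_at probe set (call lost without such probe sets); 4 were lower when adjusted over the list alone. The erythroid list had a median of -0.81 (camera, adjusted p = 5.05e-05), a call lost with an estimated correlation (adjusted p = 0.215).

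Cell cycle genes were higher in CD34+CD10-CD62Lhi cells, with a median difference of 2.72. BUB1B, a mitotic checkpoint kinase, UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, NUSAP1, a spindle protein, and CCNB2, a mitotic cyclin, differed by 3.46, 3.37, 3.17 and 3.09. These 4 of 25 measured genes were called over all genes, 22 when adjusted over the list alone and 17 with the replicate block, and all 25 had a positive difference. Camera gave an adjusted p = 1.21e-24 for the list, and an adjusted p = 0.203 with an estimated correlation. By fry the adjusted p was 0.0375; of the 13 lists that passed camera here, 4 passed fry.

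Among the 10 largest increases, CSTA (cystatin A), MPEG1 (a perforin-like protein of phagocytes), RNASE6 and ALOX5AP (the 5-lipoxygenase activating protein) differed by 5.25 ± 0.87, 4.43 ± 0.83, 4.70 ± 0.64 and 4.72 ± 0.59. IRF8, a transcription factor of monocytes, dendritic cells and early B cells, was higher by 4.69 ± 0.85 (adjusted p = 0.0401). JCHAIN, the immunoglobulin joining chain, differed by 4.95 ± 0.77, and NIBAN3, RUBCNL and PTPRS by 5.18, 5.01 and 4.44; the call of PTPRS was lost without _s_at probe sets (adjusted p = 0.829). Of 13 plasmacytoid dendritic cell markers, IRF8 was called, and 8 were higher when adjusted over the list alone and 4 with the block. CLEC4C, a lectin of plasmacytoid dendritic cells, differed by 4.51 ± 1.12 (adjusted p = 0.113, and 0.0486 with the block). The list's median was 1.55 (camera, adjusted p = 7.42e-08, and adjusted p = 0.215 with an estimated correlation). Among 15 granulocyte-monocyte progenitor genes 0 were called, 3 were higher when adjusted over the list alone and 2 with the block, with a median of 0.86 (camera, adjusted p = 1.53e-05, and adjusted p = 0.215 with an estimated correlation). MPO, the peroxidase of neutrophil granules, was at 12.83 ± 0.01 against 9.19 ± 3.63 (adjusted p = 0.323), and RNASE2 differed by 4.42 ± 1.32 (adjusted p = 0.187, and 0.0415 with the block). Markers of mature monocytes and mature neutrophils had medians of -0.05 and -0.22, with 0 of 8 and 0 of 9 called (camera, adjusted p = 0.602 and 0.242); the mean of the monocyte list, 0.18, had the other sign.

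DNTT, the terminal transferase that adds nucleotides at V(D)J joints, was at 12.41 ± 0.39 against 10.09 ± 2.74, a difference of 2.32 ± 1.07 (adjusted p = 0.449). IL7R, a receptor chain needed for lymphoid growth, was at 6.64 ± 1.19 against 4.64 ± 1.21 (adjusted p = 0.276, and 0.0244 with the block). Of 19 early lymphoid genes 0 were called over all genes or adjusted over the list alone, and 2 were higher with the block; 17 had a positive difference. The median was 0.59 (camera, adjusted p = 8.97e-05, and adjusted p = 0.215 with an estimated correlation). Among 11 V(D)J recombination genes 0 were called (1 with the block), with a median of 0.70 (camera, adjusted p = 0.00114, and adjusted p = 0.22 with an estimated correlation). BLNK, an adaptor of the pre-B cell receptor, was higher by 4.69 ± 0.81, and FOXO1, a transcription factor of B-cell and stem cell programmes, was lower by a difference of -2.54 ± 0.26. They were the 2 of 22 B-lineage genes called (2 higher and 1 lower with the block), and the list did not pass (median 0.20, adjusted p = 0.11). PAX5 (5.01 ± 0.40 against 4.49 ± 0.57), EBF1 (6.08 ± 1.55 against 4.38 ± 1.10) and RAG1 (6.74 ± 1.41 against 6.41 ± 1.90) were not called, nor were RAG2, CD79A, VPREB1, FLT3, CEBPA, GATA1 or CD7.

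Other lists that passed camera here lost the call with an estimated correlation. Cytokine receptors, with 0 of 15 called and 5 with the block, had a median of 0.36 (adjusted p = 0.00139, with an estimated correlation adjusted p = 0.215), with CSF1R, the receptor of macrophage colony-stimulating factor, at 2.60 ± 0.53 (adjusted p = 0.0599, and 0.00433 with the block). Homing and adhesion receptors had a median of 0.43 (adjusted p = 0.0236, with an estimated correlation adjusted p = 0.215); ITGB7, a chain of gut-homing integrins, was the 1 of 14 called (2 with the block), at 2.82 ± 0.30. MHC class II genes had a median of 0.38 and 0 of 11 called (adjusted p = 0.00677, with an estimated correlation adjusted p = 0.253). Immediate early and stress genes had a median of -1.08 and 0 of 13 called, 3 with the block (adjusted p = 0.000738, with an estimated correlation adjusted p = 0.22), and endothelial markers a median of -0.60 and 0 of 9 called, 1 with the block (adjusted p = 0.00307, with an estimated correlation adjusted p = 0.215). Lists of mature B cells, plasma cells, T-lineage cells, NK cells, eosinophils, basophils and mast cells, stromal cells and the NOTCH pathway did not pass, with adjusted p from 0.067 (plasma cell markers, with JCHAIN called) to 0.52 (NK cells, whose median of -0.10 and mean of 0.37 differed in sign). GATA2, a stem and mast cell transcription factor in the mast cell list, was lower, at -3.25 ± 0.56. MEIS1, in the HOXA list that was too short to test, differed by -2.21 ± 0.43 (adjusted p = 0.0508, and 0.00243 with the block).

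In all, limma called 191 genes in this comparison, 113 higher and 78 lower in CD34+CD10-CD62Lhi cells, and 2283 had an unadjusted p under 0.05. With the replicate block 856 were called, 548 higher and 308 lower, the 191 among them. With single arrays left out the count ran from 31 to 278, and without the 3 arrays numbered 1, a choice made after seeing the data, limma called 0 genes (1773 at an unadjusted p under 0.05). No other number was left out as a set, so this does not show that the calls depend on number 1. Of 32 named genes called, 9 stayed called with each of the 9 arrays left out, CRHBP, ALDH1A1, NIBAN3, RUBCNL, PTPRS, FOXO1, TAL1 and ITGB7 among them. The calls of CSTA and SELP were kept in 2 of those 9 fits, of IRF8, MPEG1, HLF, BUB1B and NUSAP1 in 1, and of RAB27B in 0. Those fits left out the replicate number. With the block and all 9 arrays, limma gave an adjusted p = 0.00782 for CSTA and 0.00665 for IRF8.

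The comparison of CD34+CD10+ with CD34+CD38- cells sets cells with an antigen of B-lymphoid progenitors against the stem cell fraction. B-lineage genes were higher in CD34+CD10+ cells: 17 of 22 measured were called higher and 0 lower, and 19 were higher when adjusted over the list alone. PAX5 and EBF1, transcription factors that set B-cell identity, were at 10.45 ± 0.57 and 10.62 ± 0.89 against 4.49 ± 0.57 and 4.38 ± 1.10 (SD, n = 3), both not above background there, differences of 5.96 ± 0.39 (adjusted p = 0.000252) and 6.24 ± 0.81 (adjusted p = 0.00372). LEF1, a transcription factor of WNT signalling in early lymphocytes, and POU2AF1, a B-cell coactivator, differed by 6.43 ± 0.82 and 6.41 ± 0.47. VPREB1, the surrogate light chain, and CD79A, a signalling chain of the B-cell receptor, differed by 4.58 ± 0.51 and 2.78 ± 0.50. The list's median was 3.10 (camera, adjusted p = 2.64e-29, and adjusted p = 0.0138 with an estimated correlation). RAG1 and RAG2, which together cleave DNA in V(D)J recombination, differed by 5.49 ± 0.94 and 5.96 ± 0.61. They were the 2 of 11 V(D)J genes called, 5 when adjusted over the list alone and 5 with the block, with a list median of 0.96 (camera, adjusted p = 8.4e-05, and adjusted p = 0.245 with an estimated correlation). Early lymphoid genes had 3 of 19 called, RAG1, RAG2 and LTB, with a median of 0.60; adjusted over the list alone, or with the block, 5 were higher and 1 lower. Camera gave that list an adjusted p = 0.000161, and an adjusted p = 0.245 with an estimated correlation. LTB (2.11 ± 0.49) rests on an _s_at probe set, and another of its probe sets had the opposite sign. DNTT was at 13.44 ± 0.39, a difference of 3.36 ± 1.07 (adjusted p = 0.148, and 0.0351 with the block), and IL7R at 7.18 ± 0.62, a difference of 2.55 ± 0.70 (adjusted p = 0.0924, and 0.00461 with the block). CHST15, NPY, HMHB1 and RUBCNL were also among the 10 largest increases, at 5.49, 5.37, 5.26 and 5.47.

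Stem cell genes were lower in CD34+CD10+ cells, with 11 of 19 called, 15 when adjusted over the list alone, and a median of -2.85 (camera, adjusted p = 8.42e-20, and adjusted p = 0.0152 with an estimated correlation). CRHBP, MYCT1 and MLLT3, a regulator of stem cell self-renewal, differed by -5.80 ± 0.54, -4.72 ± 0.65 and -4.36 ± 0.38. HOPX differed by -4.85 ± 0.30 on an _s_at probe set, while another of its probe sets did not show the drop. MPO (-0.94 ± 1.38, adjusted p = 0.904) was not called. Among 10 megakaryocyte genes 4 were lower, SELP, RAB27B, ITGA2B and VWF (von Willebrand factor), and 7 when adjusted over the list alone, with a median of -1.80 (camera, adjusted p = 1.72e-06, and adjusted p = 0.0155 with an estimated correlation). The erythroid list had 3 of 16 lower, SLC40A1 (the iron exporter ferroportin), TAL1 (call lost without _s_at probe sets) and BLVRB (a biliverdin reductase), at -4.36, -2.95 and -1.34, and a median of -1.04 (camera, adjusted p = 2.63e-05, and adjusted p = 0.245 with an estimated correlation). Of 9 eosinophil, basophil and mast cell genes 3 were lower, FCER1A (a chain of the IgE receptor), GATA2 and CPA3 (a mast cell peptidase), with -4.52, -3.99 and -3.65; the call of FCER1A was lost without _s_at probe sets (adjusted p = 0.814). The list median was -1.10 (camera, adjusted p = 0.0245, and adjusted p = 0.509 with an estimated correlation).

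Some cytokine receptors and immediate early genes were lower in CD34+CD10+ than in CD34+CD38- cells. IL6R, KIT (the stem cell factor receptor), CSF2RB (the shared chain of the IL-3, IL-5 and GM-CSF receptors) and CSF3R (the G-CSF receptor) differed by -4.91 ± 0.54, -2.86 ± 0.43, -2.73 ± 0.62 and -2.20 ± 0.50. These 4 of 15 cytokine receptors were called, and 6 were lower and 1 higher with the block or adjusted over the list alone, with a median of -0.74 (camera, adjusted p = 0.00588, and adjusted p = 0.315 with an estimated correlation). NR4A2, FOSB and FOS, transcription factors induced within minutes of a stimulus, differed by -4.47 ± 0.55, -3.77 ± 0.54 and -2.67 ± 0.61. They were the 3 of 13 immediate early and stress genes called, 8 when adjusted over the list alone and 6 with the block (median -1.19, camera, adjusted p = 4.78e-06, and adjusted p = 0.245 with an estimated correlation). SOCS3, a feedback inhibitor of cytokine signalling, EREG (epiregulin), SRGN (serglycin), ANXA1 (annexin A1), OBSL1 and NPR3 were among the 10 largest decreases, from -6.12 (SOCS3) to -4.76 (NPR3). Granulocyte-monocyte progenitor genes had LYZ (lysozyme) and CSF3R lower and GFI1, a repressor shared by myeloid and lymphoid progenitors, higher; the list (median -0.74) passed camera with an adjusted p = 0.0432, but not with the block (adjusted p = 0.0735) or with an estimated correlation (adjusted p = 0.598). Cell cycle genes were higher, with 7 of 25 called, 12 when adjusted over the list alone and 15 with the block, and a median of 1.80; RRM2 (ribonucleotide reductase), MKI67 and BIRC5 differed by 3.13, 3.12 and 3.02. Camera gave that list an adjusted p = 9.16e-15, and an adjusted p = 0.245 with an estimated correlation. MHC class II genes, with 0 of 11 called and a median of 0.34, passed (adjusted p = 0.0384), but not with the block (adjusted p = 0.072) or with an estimated correlation (adjusted p = 0.509).

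The other 11 lists did not pass, with adjusted p from 0.108 (mature B cell markers, in which FCRL1 was higher by 3.41 ± 0.53) to 0.969 (T-lineage, NK cell and mature neutrophil markers). Single members were called in some of them: FKBP11 lower among plasma cell markers, DTX1, a regulator of NOTCH signalling, higher by 3.04 ± 0.36, ESAM lower among endothelial markers, and the adhesion receptors CD44 and ITGB2 lower by differences of -2.28 and -1.86. The median, mean and test differed in sign for the T-lineage, NK cell, plasmacytoid dendritic cell, mature monocyte, mature neutrophil and homing lists. Of the 12 lists that passed camera, 6 passed fry, cell cycle genes not among them (adjusted p = 0.063). Altogether limma called 784 genes, 265 higher and 519 lower in CD34+CD10+ cells. With the replicate block the numbers were 1771, 675 and 1096, and the 784 were among them. Leaving out single arrays gave counts from 362 to 657, and leaving out the 3 arrays numbered 1 gave 184. Of 57 named genes called, 36 stayed called with each array left out, PAX5, EBF1, POU2AF1 and CRHBP among them, while LYZ, CSF3R, VWF and ESAM did in 1 of the 9 fits.

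The comparison of CD34+CD10+ with CD34+CD10-CD62Lhi cells sets cells with CD10 against CD62Lhi cells sorted without it. Whether one of these populations gives rise to the other cannot be read from the arrays. B-lineage genes were higher in CD34+CD10+ cells, with 14 of 22 called higher and 0 lower; adjusted over the list alone, or with the block, 16 were higher and 1 lower. POU2AF1, CD24 (a surface antigen of B progenitors), LEF1, PAX5 and ARPP21 differed by 5.86 ± 0.47, 5.57 ± 0.56, 5.55 ± 0.82, 5.45 ± 0.39 and 5.23 ± 0.69. EBF1, VPREB1 and CD79A differed by 4.54, 3.57 and 2.99. The list's median was 3.27 (camera, adjusted p = 3.94e-21, and adjusted p = 0.0331 with an estimated correlation). RAG1 was at 11.90 ± 0.68 against 6.74 ± 1.41 (SD, n = 3), and RAG2 at 9.24 ± 0.94 against 4.19 ± 1.09, not above background; both were called. They were the 2 V(D)J genes called of 11, and that list did not pass (adjusted p = 0.312), nor did early lymphoid genes (adjusted p = 0.679). Among the latter FLT3, a receptor of early multipotent and lymphoid progenitors, was lower, at -2.14 ± 0.39. DNTT (1.03 ± 1.07) and IL7R (0.54 ± 0.70) were not called. AKAP12, RNF152 and CHST15 were also among the 10 largest increases, at 6.10, 4.66 and 4.96. Mature B cell markers had 1 of 10 called, FCRL1, and a median of 0.42 (camera, adjusted p = 0.00854, and adjusted p = 0.528 with an estimated correlation).

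LYZ (lysozyme) was lower in CD34+CD10+ than in CD34+CD10-CD62Lhi cells, at 4.93 ± 1.77, not above background, against 12.57 ± 0.48, a difference of -7.64 ± 1.01 (adjusted p = 0.00616). CSTA, MPEG1, PTPRS, SAMHD1 and ALDH2, also among the 10 largest decreases, differed by -6.25 ± 0.87, -5.63 ± 0.83, -5.49 ± 0.48, -5.13 ± 0.92 and -5.21 ± 0.51, the call of PTPRS with the limit given above. Of 15 granulocyte-monocyte progenitor genes 3 were lower, LYZ, CSF1R and CFD (complement factor D), adjusted over the list alone 11 were lower and 1 higher, and with the block 7 and 1. The list's median was -1.71 (camera, adjusted p = 3e-07, and adjusted p = 0.428 with an estimated correlation). IRF8 was the 1 of 13 plasmacytoid dendritic cell markers called, at -3.96 ± 0.85, with 6 when adjusted over the list alone, 5 with the block and a median of -1.45 (camera, adjusted p = 3.54e-05, and adjusted p = 0.503 with an estimated correlation). Cytokine receptors had 6 of 15 called lower, 10 when adjusted over the list alone, among them CSF2RB, IL6R, CSF1R and KIT at -5.21, -4.65, -3.34 and -2.61, and a list median of -0.98. Camera gave that list an adjusted p = 5.07e-08, an adjusted p = 0.157 with an estimated correlation, and fry an adjusted p = 0.00846. The mast cell genes FCER1A and CPA3 differed by -5.54 ± 0.87 and -5.11 ± 0.78, although the drop of FCER1A was absent when _s_at probe sets were left out. ITGB2, ITGB7 and CD44 were lower among homing and adhesion receptors, at -3.25, -2.60 and -2.37 (4 lower and 2 higher with the block), and that list did not pass (adjusted p = 0.068). Cell cycle genes had a median of -0.55 and 0 of 25 called, 2 lower with the block (camera, adjusted p = 0.0105, and adjusted p = 0.827 with an estimated correlation).

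Stem cell genes as a list did not separate these 2 populations (median 0.02, adjusted p = 0.254), although HOPX, PROM1 and ABCB1 were lower, at -3.33, -2.93 and -1.48, and NRIP1 was higher, at 1.32. HOPX carries the same limit on its probe sets as above. The remaining lists, of plasma cell, T-lineage, NK cell, mature monocyte, mature neutrophil, erythroid, megakaryocyte, mast cell, stromal, endothelial, stress, MHC class II and NOTCH genes, did not pass, with adjusted p from 0.154 to 0.974. Of these, immediate early and stress genes (median -0.48, camera, adjusted p = 0.154) passed with the block (adjusted p = 0.0496). In that list 0 of 13 genes were called, and 4 were lower with the block. The median, mean and test differed in sign for the stem cell, NK cell, mature monocyte, erythroid, megakaryocyte, mast cell, stromal and NOTCH lists. Of the 6 lists that passed camera, 3 passed fry, and homing receptors passed fry only (adjusted p = 0.0402). In total 531 genes were called by limma, 144 higher and 387 lower in CD34+CD10+ cells. With the replicate block 1407 were called, 376 higher and 1031 lower, the 531 among them. Single arrays left out gave 238 to 568, and 54 were called without the 3 arrays numbered 1. Of 45 named genes called, 27 stayed called with each array left out, POU2AF1, PAX5, LYZ and CSTA among them; RAG1 did in 3 of the 9 fits, and IRF8 and NRIP1 in 2.

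**Figure D3:**
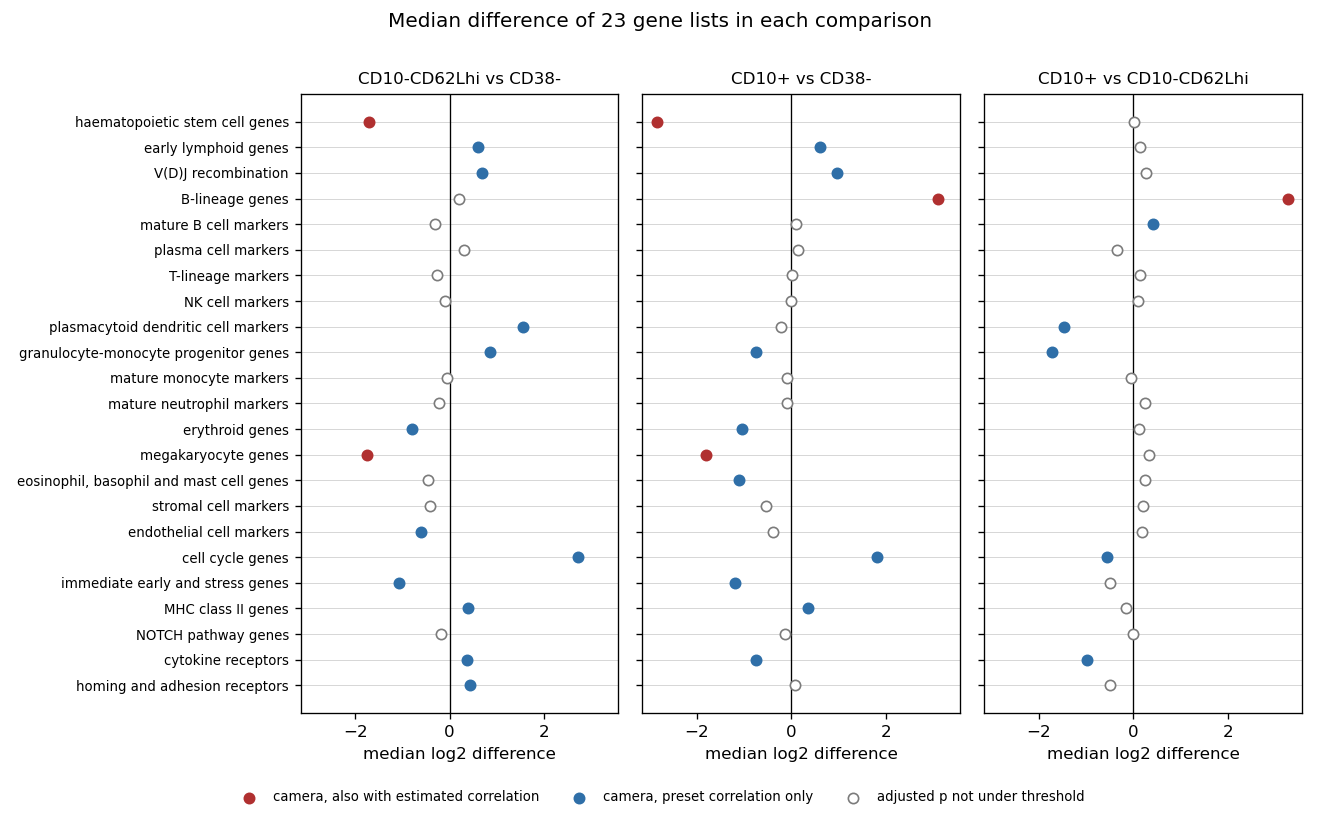
Median log2 difference (horizontal axis) over the measured members of each of 23 gene lists (vertical axis) in the 3 comparisons. Filled dots passed camera, in red also with an estimated correlation, and open dots did not; stem cell genes lay at -1.70, -2.85 and 0.02 and B-lineage genes at 0.20, 3.10 and 3.27 from left to right.

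Changes from CD34+CD38- cells overlapped between the other populations. Of the 113 genes higher in CD34+CD10-CD62Lhi cells, 55 (48.7%) were also called higher in CD34+CD10+ cells, RUBCNL and NIBAN3 among them, and of the 78 lower genes, 61 (78.2%) were also called lower, CRHBP, MYCT1 and TAL1 among them; 1 gene was called in opposite directions. Independent lists of these sizes would share 1.52 and 2.05 genes, and 100 simulated sets of unchanged populations against the same CD34+CD38- arrays shared 0.01 and 0 on average. The former figure leaves out the shared arrays and the latter leaves out the effects, so the excess over either is no measure of a shared effect. Across genes, which are not independent replicates, the differences correlated with r = 0.499 (0.5 in the simulation), and their covariance was 0.236 against 0.0822 simulated, a difference of 0.154. With 3 CD34+CD38- arrays the controls could not be split, so part of the excess in shared calls can come from sharing them. The simulated covariance already holds that sharing, as far as the simulated noise is like that of the data. On a scale where 0 is the CD34+CD38- mean and 1 the CD34+CD10+ mean, the CD34+CD10-CD62Lhi arrays lay at 0.462 ± 0.0893 (SD, n = 3) for the 265 genes higher in CD34+CD10+ cells and at 0.390 ± 0.0146 for the 519 lower genes. Populations simulated as equal to CD34+CD38- lay at 0.0948 and 0.0774. In the fit with the replicate block 239 higher and 224 lower genes were shared, with single arrays left out 10 to 80 and 8 to 71, and without the 3 arrays numbered 1 limma gave 0 and 0 (1773 genes had an unadjusted p under 0.05 in CD34+CD10-CD62Lhi vs CD34+CD38-). The position for higher genes ran from 0.228 to 0.637 with single arrays left out and was 0.171 without the arrays numbered 1; that for lower genes ran from 0.319 to 0.472.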

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

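The tests on splits with every replicate number in each group, on array processing, on donors, on monocytes, neutrophils and dendritic cells and on the base of the logarithm were chosen after the results were seen; the other splits of the arrays were planned before. The BioB covariate was added after the replicate numbers were seen to matter, with its prediction written before its result. Probe sets that carry no gene name here, or several, were outside the comparisons and are listed because some of the 13507 passed the threshold when tested apart: 9 in CD34+CD10-CD62Lhi vs CD34+CD38-, 67 in CD34+CD10+ vs CD34+CD38- and 23 in CD34+CD10+ vs CD34+CD10-CD62Lhi. These are 0.0666%, 0.496% and 0.17% of them, against 0.968%, 3.97% and 2.69% of the named genes.

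The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. In each of the 3 comparisons 1 split, the real one, gave as many genes: 191, 784 and 531 genes, against 0 in the highest of the other splits. For the F-test, 1 of 100 drawn splits of the 9 arrays, the real one with 898 genes, gave as many. The highest other split, with 510 genes, is the one that follows the replicate numbers, so splits that ignore the numbers are no fair measure. Of all 36 splits that put every number into each group, 1, the real one, gave as many (a share of 0.0278), and the next highest had 151, so chance assignment to groups is argued against there. By the same test 2324 genes differed with the replicate block.

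Arrays with the same replicate number deviated together. The BioB hybridisation control, bacterial RNA added to each sample just before hybridisation, averaged 11.47 ± 0.28 (SD, n = 3) on arrays numbered 1, 9.67 ± 0.41 on those numbered 2 and 7.89 ± 0.17 on those numbered 3. Its mean square between numbers was 103 times that within numbers, and 1 of 36 reassignments of numbers within populations (0.0278), the real one, gave as much, with 12 as the next highest, which is consistent with arrays of one number having been processed together. A differing amount of labelled RNA against the hybridisation controls stays open in part. From number 2 to 3, BioB fell in CD34+CD38-, CD34+CD10-CD62Lhi and CD34+CD10+ cells, from 9.33, 9.55 and 10.12 to 8.08, 7.73 and 7.87. BioC, another such control, went from 10.975, 11.13 and 11.68 to 11.49, 11.12 and 11.29. Such an amount would move both, so these values argue against it as the whole cause of that fall. On number 1 BioC was higher too (11.76 to 12.25), which leaves it open there. The BioB level as a covariate gave 1048 genes in CD34+CD10+ vs CD34+CD38- and the block 1771. Counts from fits with 1 linear term and with 2 block terms are not of the same form. The bound set for them therefore decides nothing. One donor behind each number, the biological reading, cannot be told apart from shared processing, because both would follow the number and give correlations like the lowest one seen, 0.362. The difference between 3' and 5' control probe sets, a measure of RNA integrity, also differed between numbers. Its means on numbers 1, 2 and 3 were 2.57, 2.90 and 1.81 for ACTB and 0.60, 1.26 and -0.02 for GAPDH. Whether RNA integrity, or the narrower spread of values on arrays numbered 1, has a part in the shared deviations was not tested.

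CSTA, MPEG1, RNASE6 and IRF8, each known from myeloid or dendritic cells, were called higher in CD34+CD10-CD62Lhi than in both other populations. Mature monocytes in an amount that raises their markers together are argued against, as cells that bring all their abundant transcripts would do. Their 8 measured markers had a median difference of -0.0506 ± 0.34 from CD34+CD38- cells (SE over markers, which are not independent replicates). In CD34+CD10-CD62Lhi cells 2 of the 8 were above the level of genes of other tissues. S100A8, not above it in any population, had the largest positive difference, 2.05 ± 0.65 (limma, adjusted p = 0.212). A median over markers mostly near background cannot exclude a minor admixture. Mature neutrophils are argued against in the same way and with the same limit, with -0.215 ± 0.129 over 9 markers, of which 1 lay above that level. The CD34 sort is meant to remove both cell types, but its purity was not tested. Plasmacytoid dendritic cells or their precursors stay open. The 13 markers had medians of 1.55 ± 0.553 against CD34+CD38- and 1.45 ± 0.574 against CD34+CD10+ cells. With an estimated correlation, however, the adjusted p by camera was 0.215 and 0.503. The CD34 sort is meant to remove mature cells of this type too, but not CD34+ precursors. Of the 13, 10 lay above the level of other tissues in the gate and 5 already did in CD34+CD38- cells. A progenitor programme shared with dendritic cells, which the design's populations could hold, was not tested apart from such cells.

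The deposited intensities exceed the range of a 16-bit scanner. At least 517 values on each array do so, and the natural logarithm of the highest is 15.03 where its log2 is 21.69, which is consistent with log2 values having been turned linear with base e. No biological explanation was tested for this.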

How the results depend on the processing

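The alternatives with the BioB covariate, without the arrays numbered 1, with the block and a minimum difference together, and with the size threshold on the other log scale were chosen after the data were seen. In order, the counts below are those for CD34+CD10-CD62Lhi vs CD34+CD38- (191), CD34+CD10+ vs CD34+CD38- (784) and CD34+CD10+ vs CD34+CD10-CD62Lhi (531). With the replicate block they were 856, 1771 and 1407, the F-test gave 2324, 239 higher and 224 lower calls were shared, and the positions of CD34+CD10-CD62Lhi were 0.562 and 0.347 for genes higher and lower in CD34+CD10+. The block ended the list calls of granulocyte-monocyte progenitor (adjusted p = 0.0735) and MHC class II genes (adjusted p = 0.072) in CD34+CD10+ vs CD34+CD38- and added that of immediate early and stress genes in CD34+CD10+ vs CD34+CD10-CD62Lhi (adjusted p = 0.0496). Among named genes it ended 0 calls by limma and added 13, 9 and 11 in the 3 comparisons. With the replicate block and a difference of at least 1 the counts were 822, 1614 and 1308, the shared calls 224 higher and 210 lower, and the positions 0.556 and 0.345. The BioB covariate gave 317 for the first comparison, 93 and 98 shared calls and a lower-gene position of 0.375. Without the 3 arrays numbered 1 limma called 0 (1773 at an unadjusted p under 0.05), 184 and 54 genes and 107 by the F-test. In that setting 0 calls were shared in either direction, and the positions were 0.171 and 0.446. Fewer arrays are part of that construction, and no other number was left out as a set for comparison. Fits of only the 2 populations compared gave 57, 370 and 517 in the 3 comparisons. Each had fewer arrays to estimate variances. The third count hardly changed, but only 413 of its 531 main calls were kept. How far the number of arrays accounts for the falls was not tested. Leaving out dim genes gave 310 in the first comparison, 86 shared higher calls and a lower-gene position of 0.364. Without _x_at and _s_at probe sets the third comparison had 319 genes and the F-test 586, with 36 shared higher calls and a lower-gene position of 0.405; 17066 genes were tested. Array weights gave 904 in the third comparison and a lower-gene position of 0.367; that position was 0.431 with the mean of probe sets, 0.415 with quantile normalization and 0.358 with median centring. Where no construction is named, the cause was not tested.

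Without _x_at and _s_at probe sets 4 differences reversed sign: HOPX in CD34+CD10+ vs CD34+CD38- (0.17, from -4.85) and vs CD34+CD10-CD62Lhi (0.34, from -3.33), LTB in CD34+CD10+ vs CD34+CD38- (-0.28, from 2.11) and FCER1A in CD34+CD10+ vs CD34+CD10-CD62Lhi (0.20, from -5.54). In that setting 6, 9 and 4 other calls of named genes were lost in the 3 comparisons. Named genes with only _x_at or _s_at probe sets, such as BLNK, drop out of it, so their calls could not be checked in this way. FCER1A in CD34+CD10+ vs CD34+CD38- was at -0.25 (adjusted p = 0.814), TAL1 at -0.66 and -0.27 (adjusted p = 0.478 and 0.873) against CD34+CD38- cells in CD34+CD10-CD62Lhi and CD34+CD10+ cells, and PTPRS at 0.17 and -0.02 (adjusted p = 0.829 and 0.988) in CD34+CD10-CD62Lhi vs CD34+CD38- and CD34+CD10+ vs CD34+CD10-CD62Lhi. These take another probe set of the gene. The others were MPEG1, RAB27B, BUB1B and NUSAP1 (adjusted p = 0.0506 to 0.122) in the first, LYZ, VWF, ESAM, BIRC5, NUSAP1, FOS and CSF2RB (0.0522 to 0.111) in the second and CD2, IRF8 and SPARC (0.0558 to 0.0613) in the third comparison, and the granulocyte-monocyte list call in the second was lost too (0.0777). Of these, SPARC took another probe set with a smaller difference (-1.49, from -3.10), and NUSAP1 (3.36 and 2.94, from 3.17 and 3.01) and BIRC5 (2.90, from 3.02) differed slightly. The other 10 kept their differences, such as 4.43 for MPEG1 and -4.28 for LYZ, so their loss does not speak for shared probes. Over all alternatives, named genes kept their side of the threshold in 4764 cases, were stronger in 138 and weaker in 500, and lists in 1413, 29 and 70. These totals include genes and lists not called in the main fit, which could not become weaker. They therefore overstate how stable the calls were. Of 134 calls of named genes in the main fit, 72 were kept with each of the 9 arrays left out.

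With single arrays left out, the counts ran from 31 to 278, 362 to 657 and 238 to 568, the F-test from 442 to 798, shared higher calls from 10 to 80, shared lower calls from 8 to 71, and the positions from 0.228 to 0.637 and 0.319 to 0.472. Arrays that moved a count by more than 1.5 times were, in the first comparison, CD34+CD38- replicates 1 (58) and 3 (81), CD34+CD10-CD62Lhi replicates 1 (74), 2 (40) and 3 (31) and CD34+CD10+ replicates 2 (125) and 3 (104). In the second they were CD34+CD38- replicate 3 (511) and CD34+CD10+ replicates 2 (458) and 3 (362), and in the third all of CD34+CD10-CD62Lhi (247, 238 and 244) and of CD34+CD10+ (322, 324 and 276). The F-test count moved without each CD34+CD10-CD62Lhi array (557, 535 and 484) and each CD34+CD10+ array (596, 543 and 442). Fewer arrays lower the precision; the cause of the differences between arrays was not tested. Calls kept with each array left out were 9 of 32, 36 of 57 and 27 of 45 for named genes and 11 of 13, 8 of 12 and 5 of 6 for lists in the 3 comparisons. Signal over background limits dim genes: 11069 of 19738 genes had a population mean above the level of genes of other tissues.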

Other observations

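Genes in which CD34+CD10-CD62Lhi cells stood apart from both other populations were picked out after their values were seen. By limma 33 genes were called higher in these cells than in both others and 13 lower (169 and 36 with the replicate block), where independent lists would share 2.22 and 0.569 and simulated unchanged populations shared 0 and 0. Both comparisons use the same CD34+CD10-CD62Lhi arrays, which the former figure leaves out, and the simulation leaves out the effects, so neither is a measure of chance for these counts. With single arrays left out the counts ran from 8 to 52 and from 2 to 12, and without the 3 arrays numbered 1 limma gave 0 and 0 (1773 genes had an unadjusted p under 0.05 against CD34+CD38- cells). No gene list was tested on them. FCER1G and TYROBP, signalling chains of activating receptors, were higher than in CD34+CD38- cells by 3.58 ± 0.42 and 1.90 ± 0.36 (SE) and than in CD34+CD10+ cells by 4.53 ± 0.42 and 2.97 ± 0.36. LY86, a partner of a toll-like receptor relative, LGMN (legumain, a lysosomal protease), IL10RA and SIGLEC5 exceeded CD34+CD38- cells by 3.43, 3.02, 2.94 and 1.25 and CD34+CD10+ cells by 2.36, 2.84, 3.35 and 1.42. HERPUD1 and SEC11C, of protein handling in the endoplasmic reticulum, exceeded CD34+CD38- cells by 3.28 and 1.40 and CD34+CD10+ cells by 2.32 and 1.64.

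Of the 13 genes lower than in both, FOXO1 and SESN3, one of its known targets, differed from CD34+CD38- cells by -2.54 ± 0.26 and -1.37 ± 0.25 and from CD34+CD10+ cells by -4.08 ± 0.26 and -1.53 ± 0.25. SOCS2, a feedback inhibitor of cytokine signalling, ERG, an ETS transcription factor of stem cells, RHOB, a small GTPase, and PRKCH, a protein kinase C, differed from CD34+CD38- cells by -2.57, -1.87, -2.93 and -1.59 and from CD34+CD10+ cells by -3.88, -2.38, -3.39 and -1.65.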
